A study of Mus musculus with 6 samples.

How the data were processed

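Total RNA was extracted with Trizol, treated with DNase and depleted of ribosomal RNA (RNase H or Ribo-Zero) before library preparation, per the labels. The 6 libraries come from the basal part of the cochlea of C57BL/6J mice, 3 young and 3 old, and each was sequenced as its own sample. Ages, sex, strandedness, sequencing dates, aligner, quantifier and annotation are not given in the sources used here. The genome build was GRCm38.p6, per the notes of the authors.

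The deposited count table holds estimated counts per gene and library that the authors computed and did not scale; 20.2% of the gene values are not whole numbers. The authors also deposited FPKM values (fragment counts scaled by transcript length and library total), which were used only in alternatives and to compute an implied effective length per feature from counts and FPKM. The count table has 42623 entries, 34395 for genes and 8228 for circular RNAs, which have no FPKM. Of the gene entries 28330 carry an NCBI gene identifier, and 28251 of these were found in the RefSeq table of the same build, which gave symbols, classes and positions. The other 6065 carry identifiers that start with BGIG and were kept as unnamed features. RefSeq classed 18688 genes as protein coding and 9228 as long noncoding. Circular RNA entries were left out of the gene test and tested on their own. No gene of the mitochondrial genome is among the entries, and the list of mitochondrial genes was not analysed here.

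Estimated counts were rounded and compared with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM scaling, quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment over the 20157 genes that passed the filter, at an adjusted p under 0.05. Log2 fold changes are old minus young, a value after ± is the SE for a log2 fold change and the SD over 3 libraries for CPM or percent. The SE was derived from the fold change and its F statistic. CPM used TMM-scaled library totals. The common biological coefficient of variation was 0.134. The labels give replicate numbers to both groups, and the genes of like-numbered libraries were checked for pairing. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with estimated correlations and fry as alternatives, and adjusted over the 39 lists. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots.

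The comparison, tests, thresholds, gene lists and the rule for named genes were set before the data were examined. The rule took Mirg, Foxp1 and the Dlk1-Dio3 genes. It further took the 12 genes with the largest changes in each direction among named genes that passed, had a mean of at least 5 CPM in the higher group and did not overlap between groups. To these it added up to 4 members per list with the largest changes among those that passed, and the 4 long noncoding genes with the largest changes in each direction at a mean of at least 1 CPM. Where 5 or fewer members of a list moved in a direction, members outside the rule are named after their values were seen. Some genes that the rule or these counts would name are not reported here. A fold against a group without counts was taken against 3 counts over the group and is a lower bound. Ratios with 1 to 3 counts in a group have a 95% interval. Floors and intervals cover counting error only. The lists covered hair cells, supporting cells, spiral ganglion neurons, Schwann cells and myelin, marginal cells, melanocytes, fibrocytes, macrophages, neutrophils, B lineage, T and NK cells, erythroid cells, osteoblasts, osteoclasts, muscle and endothelium. They further covered interferon response, antigen presentation, complement, cytokines, senescence, proliferation, collagen, oxidative phosphorylation, antioxidants, heat shock, apoptosis, autophagy, clock, immediate early genes, ion transport, ribbon synapse, deafness, imprinting, nuclear long noncoding RNAs, Foxp and Foxo, ribosomal proteins and histones.

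The gene totals per library ran from 26245416 to 39433584 counts. The fit was tested on simulated data with the same number of libraries and genes, in which 200 genes were changed. It called 44% of the genes changed by 1.5-fold, 60% at 2-fold, 98% at 4-fold and 98% at 8-fold. It also called 22 unchanged genes, 12.8% of its calls, a share above the adjusted p threshold used. In those data 3 of 39 lists were called. In the measured data far more genes changed, 10923 of 20157, and adjusted p-values depend on how many genes change. The simulated shares therefore do not give the sensitivity or the share of false calls of the fit to the measured data. Alternatives were DESeq2 size factors, upper-quartile scaling, library totals alone, no filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom with and without quality weights, a replicate block, and removal of globins and the 10 features with the most counts. Further ones were limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), stricter and unadjusted thresholds, and the omission of each library. Added after the data were seen were the omission of genes of chromosomes X and Y, inclusion of circular RNAs, thinning of each library to 26245396 counts, TMM on protein-coding genes, library totals alone without globins and those 10 features, offsets for implied length, and totals of the circular RNAs themselves.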

Results

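RNA of the basal part of the cochlea was measured in 6 libraries from C57BL/6J mice, 3 labelled young and 3 labelled old. C57BL/6J is an inbred strain with early hearing loss that begins at the cochlear base, and the series is about age-related hearing loss. The labels give neither the ages nor the sex of the animals. They also do not say whether each library came from a separate animal, so the p-values measure only the spread between these libraries. Gene counts added up to 37084017, 39433584 and 38086124 in young 1, 2 and 3, and to 26814638, 26839068 and 26245416 in old 1, 2 and 3. The first principal component held 72.1% of the variance and parted the age groups. Pearson correlations of log2 CPM (counts scaled by library total) ran from 0.979 to 0.991 within groups and from 0.934 to 0.951 between groups. They were computed across genes, which are not independent replicates.

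The groups also differed in sex-linked RNA and in make-up. Xist, the RNA that coats the inactive X chromosome of females, had counts of 18384, 15580 and 12613 in young 1, 2 and 3 and of 4, 9 and 0 in old 1, 2 and 3. The Y-linked genes Ddx3y and Kdm5d, a helicase and a histone demethylase, had a count of 0 in each young library. Ddx3y had 1027, 1107 and 868 counts in old 1, 2 and 3, and Kdm5d had 796, 675 and 817. Age group and these sex markers changed together in 6 of 6 libraries, so the comparison of old with young is also one between opposite sex-linked profiles. Long noncoding genes took 3.04% ± 0.316 of the counts in young and 5.07% ± 0.153 in old libraries (SD, n = 3 per group). Globin genes took 0.303% ± 0.113 in young and 0.084% ± 0.047 in old libraries. A single unnamed feature, BGIG10090_59442, took 8.14% ± 1.72 of the counts in young and 1.57% ± 0.263 in old libraries.

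The series title names the long noncoding RNA Mirg and the gene Foxp1, and the comparison asks how both differ between the age groups. Both rose in the old libraries. Mirg (gene 100040724, chromosome 12, 109734981 to 109749458, GRCm38.p6), a microRNA host transcript of the imprinted Dlk1-Dio3 region, had 7.46 ± 2.38 CPM in young and 23.2 ± 2.01 CPM in old libraries (SD, n = 3). Foxp1 (gene 108655, chromosome 6, 98925342 to 99522746), a forkhead transcription factor, had 168 ± 11.6 CPM in young and 310 ± 10.4 CPM in old libraries. In the edgeR model the log2 fold change of old minus young was 1.63 ± 0.20 for Mirg (SE; adjusted p = 0.000116) and 0.88 ± 0.08 for Foxp1 (adjusted p = 2.82e-05). Each old value lay above each young value for both genes, a 3.1-fold and a 1.84-fold difference of the means. The two-sided exact permutation p was 0.1 for each gene, the smallest that 3 against 3 libraries allow. The study chose both genes, so that their edgeR p-values adjusted over the 2 genes alone, 6.78e-06 and 9.23e-07, are not independent evidence. The share of long noncoding counts and the sex markers moved with both genes. In the annotation Mirg overlaps microRNA genes and Foxp1 other noncoding genes, and how reads of shared spans were assigned is not given.

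**Figure D1:**
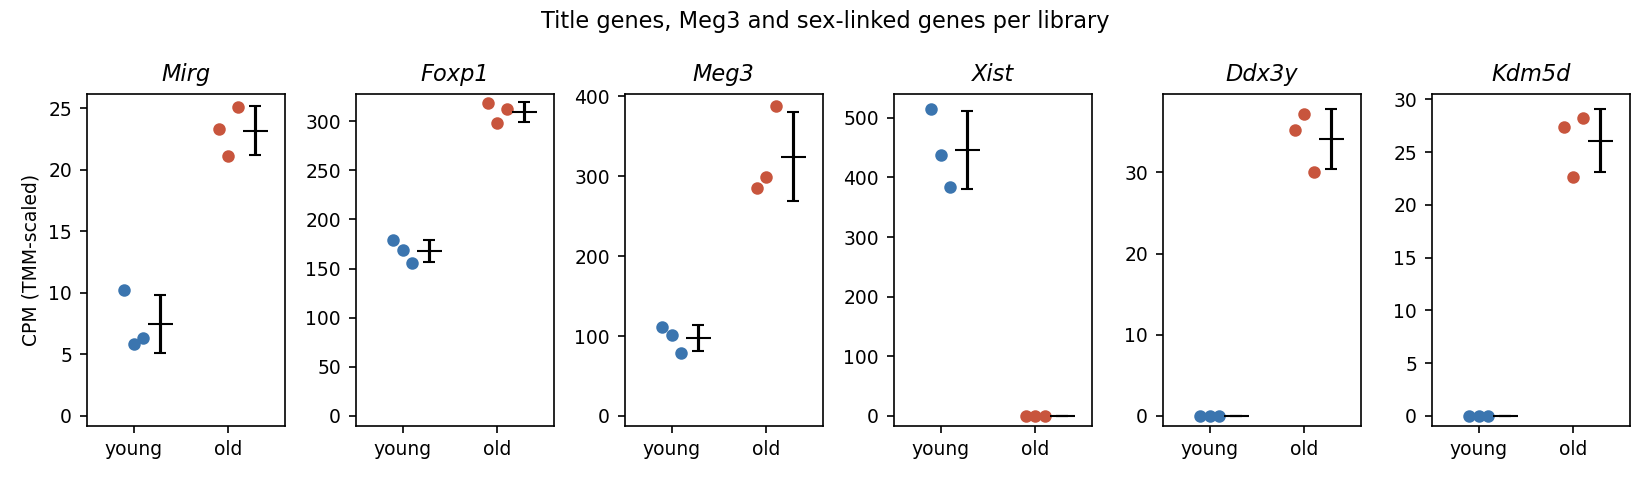
CPM (scaled by the trimmed mean of M-values, TMM) of Mirg, Foxp1, Meg3, Xist, Ddx3y and Kdm5d in each of the 3 young and 3 old libraries, one point per library, with the group mean and SD as a line with bars. Mirg, Foxp1 and Meg3 lie higher in each old library, Xist is present in the young libraries, and Ddx3y and Kdm5d have no counts in them.

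Other RNAs of the Dlk1-Dio3 region were higher in old libraries as well. Meg3 (gene 17263, chromosome 12, 109540996 to 109571729), its long noncoding RNA from the maternal chromosome, rose from 97.4 ± 16.3 to 324 ± 55.6 CPM (log2 fold change 1.73 ± 0.15, adjusted p = 2.26e-05). Rtl1, a retrotransposon-derived gene of the region, had 1 count over the young libraries, in young 2, and 749 over the old, a ratio of 888 (95% interval 159 to 35100, which covers counting error only). Its fitted log2 fold change of 9.31 was 11.06 without young 2. Rtl1 overlaps Meg3 over 6830 bases in the annotation, and its effective length implied by the counts and FPKM is 30121 bases. Strandedness is not given, so it is not known which of them the reads of the shared span come from, and the value of Rtl1 is uncertain. Dio3os had a log2 fold change of 0.71 (adjusted p = 0.119) and Begain of 0.42 (adjusted p = 0.164), and neither passed. Of 5 tested members of the region 3 rose, also adjusted over the list alone, and the list was higher (adjusted p = 5.38e-05; adjusted p = 0.32 with an estimated correlation). On log2(FPKM + 1) the list did not pass (adjusted p = 0.103). Rian, Dlk1 and Dio3 did not pass the filter on low counts.

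Among 20157 tested genes, 5427 rose and 5496 fell in the old libraries at an adjusted p under 0.05, together 54.2%. Changes of at least 2-fold numbered 2259 higher and 1240 lower. The values of the groups did not overlap for 12548 genes, 62.3% of those tested, where chance gives 10%. Of the changed genes, 49.7% were higher with TMM scaling, 73.9% with library totals alone, 62.1% with TMM on protein-coding genes and 73 to 74.1% with FPKM. These scalings moved the median log2 fold change by 0.274, 0.133 and 0.258 to 0.284, and all log2 fold changes given are relative to TMM unless another scaling is named. Which direction the coding genes took depended on the scaling: of 15316 tested, 3020 rose and 5308 fell with TMM (median -0.13), but 5325 rose and 2818 fell with library totals alone (median 0.14). With TMM on protein-coding genes 4128 of them rose and 4013 fell. On the X chromosome 135 of 589 genes rose and 183 fell with TMM (median -0.08), against 215 and 101 with library totals alone (median 0.20). On autosomes 4328 rose and 5244 fell with TMM, against 6855 and 2782 with library totals alone.

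The genes with the largest increases were Y-linked or long noncoding to a large part. Ddx3y was at least 1190-fold and Kdm5d at least 904-fold higher in old libraries, taken against a floor of 3 counts over the young group. The Y-linked translation factor gene Eif2s3y had 2 young counts, both in young 3, and a ratio of 1070 (95% interval 296 to 8850). Its fitted log2 fold change of 9.80 was 12.35 without young 3. Uty, a Y-linked histone demethylase gene with a close X-linked relative, had 90, 74 and 63 counts in young 1, 2 and 3 and rose to 81.6 ± 0.873 CPM (log2 fold change 5.22). Gm40364, a predicted coding gene on chromosome 6, was at least 288-fold higher. Glycam1, a mucin-like protein of lymph node vessels, had 17.3 CPM in old 2 against 0.961 and 1.7 in the other old libraries. Its log2 fold change of 5.93 was 3.60 without old 2 and 7.11 without young 1. The noncoding Gm51671 (5.80 ± 0.27), Gm32994 (2.81 ± 0.26) and Gm39903 (2.41 ± 0.24) rose, as did the pseudogenes Ptma-ps2 (3.75 ± 0.22) and Gm13315 (2.45 ± 0.23). Gm13315 lies inside Cacnb2. Sequence is shared within the H2bc histone genes and between Ptma-ps2 and its parent gene, and how shared reads were assigned is not given in the sources used here.

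The largest decreases came from X inactivation RNAs, replication histones, bone and blood genes, and the myelin gene Mog. Xist fell by 11.52 on the log2 scale, or by 12.59 without old 2, and its antisense Tsix, which overlaps it over 22861 bases, by 7.47; strandedness is not given, so it is not known which of them the reads of the shared span come from, and the value of Tsix is uncertain. The replication histone genes H2bc14 (-4.47 ± 0.47), H2bc9 (-4.20 ± 0.33), H2bc12 (-4.18 ± 0.47), H2bc3 (-3.99 ± 0.30) and H2bc11 (-3.89 ± 0.32) fell. Bglap, which encodes the bone protein osteocalcin, had a log2 fold change of -4.36, or -3.70 without young 3. S100a8, a calcium-binding protein of neutrophils, fell from 130 ± 28.6 to 7.04 ± 3.76 CPM (log2 fold change -4.21). The red cell gene Hemgn (-3.99) fell too. Without old 3 the values of H2bc12 and Hemgn were -5.33 and -5.51. Mog, a central myelin gene, had 15.3 CPM in young 1 against 2.53 and 1.61 in the other young libraries. Its ratio of young to old was 291 (95% interval 80.1 to 2400). The fitted value of Mog was -7.93, or -6.30 without young 1 and -10.73 without old 1, which held its old counts.

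Long noncoding genes as a class were higher in the old libraries. Of 2763 tested, 1385 rose and 109 fell, so that 92.7% of the changed ones were higher, and this share stayed between 90.5 and 96.6% in every setting run. Their median log2 fold change was 0.81, with quartiles of 0.22 and 1.26, and 999 rose and 58 fell by at least 2-fold. Gm31443 was at least 118-fold, Gm52557 at least 39.9-fold and Gm16907 at least 36.4-fold higher in old libraries. Gm33361 had a ratio of 183 (95% interval 32.3 to 7260), and its single young count was in young 2, without which the fitted 7.02 was 8.77. Without old 3 the fitted value of Gm52557 was 7.36 in place of 8.21. These 4 lie inside the coding genes Dclk1, Osbpl6, Aopep and Ank3, and how reads of the shared spans were assigned is not given, so their values are uncertain. After Xist, the largest falls were those of Gm11747 (-2.88, or -4.18 without old 3), Gm19935 (-2.78) and AI662270 (-2.67). By number, unnamed features moved in the same way, with 939 of 1869 higher and 63 lower. Their mean share of the counts was 10.6% in young and 4.08% in old libraries, of which BGIG10090_59442 alone took 8.14% and 1.57%. The list of abundant nuclear and host long noncoding RNAs had 16 of 33 members higher and 11 lower, also adjusted over the list alone, or 18 and 4 with library totals alone. It was higher as a list (adjusted p = 0.0249; adjusted p = 0.419 with an estimated correlation). It did not pass with limma-voom (adjusted p = 0.0957), on log2(FPKM + 1) (adjusted p = 0.405) or without old 3 (adjusted p = 0.0505). In it Pvt1 (1.79) rose, while Rmst (-2.13; adjusted p = 0.0189, and 0.0704 without young 2, -2.84 without old 2) and the imprinted H19 (-1.73) fell.

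**Figure D2:**
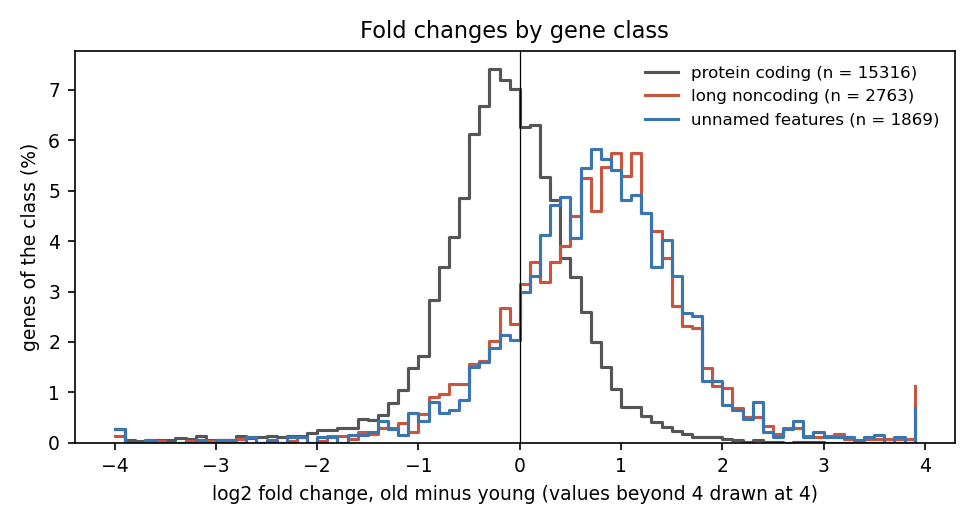
Percent of genes per bin of log2 fold change, old minus young, for 15316 protein-coding genes, 2763 long noncoding genes and 1869 unnamed features. The protein-coding median is -0.13 and that of the long noncoding genes 0.81 with TMM scaling, and 0.14 and 1.09 with library totals alone.

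Markers of sensory cells and of the lateral wall were mostly lower in old libraries. Of 33 hair cell markers 21 fell and 5 rose, or 15 and 7 with library totals alone, and the list was lower (adjusted p = 0.00649; adjusted p = 0.621 with an estimated correlation). Ocm, the calcium buffer oncomodulin of outer hair cells, fell from 18.6 ± 4.76 to 3.69 ± 1.13 CPM (log2 fold change -2.33 ± 0.25). Pjvk (-2.15), Lrrc52 (-1.96) and Strc (-1.90), whose product stereocilin links stereocilia, fell as well. The 5 that rose were Whrn (0.89), Espn (0.71), Dnm3 (0.53), Pcdh15 (0.41) and Ush1c (0.40), named after their values were seen. Of 16 markers of marginal cells of the stria vascularis, 14 fell and 2, Wnk4 among them, rose, or 9 and 2 with library totals alone, and the list was lower (adjusted p = 1.66e-05; adjusted p = 0.419 with an estimated correlation). The sodium pump subunit gene Atp1b2 (2340 ± 499 to 968 ± 156 CPM) and the endocytic receptor gene Lrp2 (4914 ± 979 to 2038 ± 26.1 CPM) were among those that fell. Melanocyte markers fell in 9 of 16 cases and none rose, or 6 and 2 with library totals alone (list adjusted p = 0.0024; adjusted p = 0.325 with an estimated correlation). They included the cation channel gene Trpm1 (-1.24) and the pigment enzyme gene Dct, which fell from 846 ± 91.4 to 423 ± 18.8 CPM. Fibrocyte markers of the spiral ligament fell in 12 of 16 cases, in 8 with library totals alone and in 6 with FPKM, among them Dkk2 (-1.84), Otor (-1.77) and the borate and water transporter gene Slc4a11 (-1.44). This list was lower (adjusted p = 2.73e-05; adjusted p = 0.325 with an estimated correlation). Without young 1, young 2 and old 2 in turn, the adjusted p was 0.0771, 0.112 and 0.0676 for Pcdh15, 0.1, 0.0824 and 0.117 for Ush1c, and 0.0913, 0.105 and 0.1 for Wnk4. Pcdh15 also missed the threshold without old 1, and Ush1c and Wnk4 without old 1 and old 3 (adjusted p from 0.0549 to 0.118). The counts of these 4 lists were the same adjusted over the list alone.

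Supporting cell markers went both ways. Of 25 tested, 6 rose and 8 fell, also adjusted over the list alone, against 9 and 5 with library totals alone, and the list did not pass (adjusted p = 0.475). The progenitor factor genes Sox2 (1.19 ± 0.13), which lies within the noncoding Sox2ot, and Hes1 (1.10 ± 0.14) rose, and the water channel gene Aqp4 (-1.53 ± 0.23) and the collagen gene Col9a2 (-0.98 ± 0.11) fell. Of 60 genes of hereditary deafness 30 fell and 9 rose, also adjusted over the list alone, but 17 fell and 17 rose with library totals alone, and of 59 tested with FPKM 15 fell and 20 rose. That list was lower (adjusted p = 0.00649; adjusted p = 0.67 with an estimated correlation and 0.0538 with fry), and its median was -0.31. It did not pass on log2(FPKM + 1) (adjusted p = 0.0664). Strc, Crym (-1.82), the outer hair cell motor gene Slc26a5 (-1.78, 28.2 ± 6.75 to 8.20 ± 2.51 CPM) and Lhfpl5 (7.56 ± 0.977 to 3.12 ± 0.123 CPM) fell most. Strc, Slc26a5, Lhfpl5 and many other deafness genes are also in the hair cell list, so the deafness list is not independent of it. Potassium and ion transport genes fell in 12 and rose in 3 of 25 cases, with 12 and 4 adjusted over the list alone, 7 and 9 with library totals alone and 5 and 10 with FPKM. The list did not pass (adjusted p = 0.0612), but did without young 1 (adjusted p = 0.0119) and without young 2 (adjusted p = 0.0497). The water channel gene Aqp1 (-1.69) and the gap junction gene Gja1 (-1.31) fell, and Kcnn2 (0.95), Kcnma1 (0.32) and Atp2b2 (0.28) rose, the last 2 named after their values were seen. Gja1 did not pass on log2(FPKM + 1) (-0.78; adjusted p = 0.0617) or log2(FPKM + 0.1) (-0.94; adjusted p = 0.0589). Kcnma1 missed the threshold without young 2, young 3 or old 3 (adjusted p = 0.0812, 0.0815 and 0.0691) and Atp2b2 without young 2, young 3 or old 1 (adjusted p = 0.104, 0.0528 and 0.0508).

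Genes of neurons and their synapses rose more often than they fell in old libraries where they changed. Of 34 markers of spiral ganglion neurons 16 rose and 3, Syt1, Pvalb and Calb2, fell, or 11 and 5 with length offsets, where the median was 0.09 in place of 0.28. The list was higher (adjusted p = 0.0216; adjusted p = 0.711 with an estimated correlation and 0.131 with fry), and passed neither without young 3 (adjusted p = 0.0557) nor without old 3 (adjusted p = 0.0697). Nefh, the heavy neurofilament gene, rose from 439 ± 107 to 1115 ± 158 CPM (log2 fold change 1.34 ± 0.17), and Prph (1.33 ± 0.24), Elavl3 (1.01 ± 0.17) and Ina (0.91 ± 0.15) rose too. Ribbon synapse genes rose in 17 and fell in 4 of 26 cases, or 14 and 4 with length offsets (list adjusted p = 0.00649; adjusted p = 0.55 with an estimated correlation). The calcium sensor gene Cabp1 (1.44 ± 0.14), the glutamate receptor gene Gria2 (1.14 ± 0.15) and the scaffold gene Shank1 (1.03 ± 0.14) rose. Grin2a (-1.99, -1.43 without old 1 at adjusted p = 0.101, -1.70 without old 2 at adjusted p = 0.148, -3.78 without old 3, and adjusted p = 0.0777 with library totals alone), the exocytosis gene Otof (-0.79), the glutamate transporter gene Slc17a8 (-0.78) and Syngr1 (-0.51) fell. Schwann cell and myelin genes did not pass as a list (adjusted p = 0.909), with 8 of 24 higher and 5 lower, or 8 and 6 adjusted over the list alone and 9 and 4 with library totals alone. Syt1 missed the threshold without young 2, young 3 or old 1 (adjusted p = 0.0713, 0.0506 and 0.0553), and Calb2 without old 2 (adjusted p = 0.057). Besides Mog, Mobp (-3.58, or -1.73 without young 1), S100b (-1.13) and Mal (-0.33, adjusted p = 0.0587 without old 2) fell. Sox10 was among the 8 that rose. Mobp did not pass with limma-voom (-2.81; adjusted p = 0.0606). Syt1, Calb2 and Mal did not pass with library totals alone (adjusted p = 0.126, 0.692 and 0.683). The counts of the neuron and synapse lists were the same adjusted over the list alone.

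Genes of blood-forming cells had the lowest list medians with TMM scaling, beside a globin share of 0.303% in young and 0.084% in old libraries. Of 22 neutrophil genes 21 fell, or 22 adjusted over the list alone, with a median of -3.43 (list adjusted p = 1.7e-20; adjusted p = 0.32 with an estimated correlation). Ly6g (-4.48), Ms4a3 (-4.41, or -6.97 without old 3) and the elastase gene Elane (-3.87, or -4.60 without old 3) fell most with S100a8. Of 22 erythroid genes 21 fell, also adjusted over the list alone, with a median of -2.88 (list adjusted p = 3.38e-09; adjusted p = 0.32 with an estimated correlation). Rhag (-5.68, or -10.31 without old 3) and the transcription factor gene Gata1 (-3.75, or -5.98 without old 3) joined Hemgn. Genes of the B lineage fell in 12 of 17 cases and 1 rose, also adjusted over the list alone, or 11 and 1 with library totals alone, with a median of -2.38 (list adjusted p = 5.38e-05; adjusted p = 0.325 with an estimated correlation). With genes of a mean count of at least 50 alone the B lineage list did not pass (adjusted p = 0.0604). The receptor chain gene Cd79b (-5.61), Vpreb3 (-5.22, or -6.45 without old 2) and Ms4a1 (-4.25, or -5.51 without old 3) fell. Dntt, the enzyme that adds bases at antigen receptor joints, had a ratio of young to old of 31.2 (95% interval 8.34 to 263), and its fitted value was -4.73, or -7.54 without old 3. Ebf1 rose from 232 ± 10.4 to 377 ± 25.4 CPM, levels far above those of the other members of the list. T and NK cell genes gave 2 higher and 2 lower of 12, also adjusted over the list alone, and no list call (adjusted p = 0.639); the median was 0.08, the mean -0.69 and the test pointed lower. The killer cell protease gene Gzma was at least 27.6-fold lower in old libraries and Nkg7 fell (-3.62 ± 0.38). Cd4 (0.67; adjusted p = 0.0198) rose, but did not pass without young 1, young 3 or old 2 (adjusted p = 0.0664, 0.0573 and 0.0741).

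Macrophage and bone markers fell more often than they rose, and endothelial and muscle markers went both ways. Of 24 macrophage genes 11 fell and 2, Trem2 and C1qc, rose, or 12 and 2 adjusted over the list alone, 9 and 2 with library totals alone and 7 and 2 with FPKM (list adjusted p = 0.00649; adjusted p = 0.55 with an estimated correlation). Clec4a2 (-2.60), the integrin gene Itgam (-1.48) and F13a1 (-1.41) fell most. Osteoblast and osteocyte genes fell in 12 of 22 cases and none rose, against 2 risen with library totals alone (list adjusted p = 3.17e-06; adjusted p = 0.325 with an estimated correlation). Osteoclast genes fell in 8 of 11 (list adjusted p = 0.000167; adjusted p = 0.32 with an estimated correlation), and 5 fell and 1 rose with library totals alone. Ibsp (-1.86 ± 0.20) of bone matrix and the bone-resorbing protease genes Mmp9 (-2.70 ± 0.20) and Ctsk (-1.45 ± 0.14) fell. Mmp9 is also in the neutrophil list and Car2 in the erythroid list, so the osteoclast list is not independent of these. Endothelial genes rose in 5 and fell in 2 of 19 (list adjusted p = 0.171, and 0.043 without young 1), with 12 higher and 1 lower under library totals alone. Sox17 (1.92 ± 0.23), Sox18 (1.33 ± 0.18), Flt1 (0.79 ± 0.10), Robo4 (0.56) and Pecam1 (0.44) rose, and Plvap (-0.66) and Kdr (-0.53) fell. Skeletal muscle genes did not pass as a list (adjusted p = 0.875), with 2 of 18 higher and 4 lower, or 4 and 4 with library totals alone. The giant sarcomere genes Neb (1.63 ± 0.18) and Ttn (1.53 ± 0.12) rose, and Acta1 (-2.78, or -1.91 without young 3 and -3.42 without old 2), Tnnt1 (-1.72), Myl1 (-1.29) and Pvalb (-0.61) fell. Acta1 did not pass with limma-voom (adjusted p = 0.0829) or on log2(FPKM + 1) (adjusted p = 0.0585). Trem2 missed the threshold without young 1, young 3 or old 2 (adjusted p = 0.0785, 0.0554 and 0.0891), and Pecam1 without young 2, young 3, old 1 or old 2 (adjusted p = 0.122, 0.0766, 0.0791 and 0.0996). Kdr did not pass with library totals alone (adjusted p = 0.214). The counts of the bone, endothelial and muscle lists were the same adjusted over the list alone.

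Genes of interferon response and of inflammation were mostly lower in old libraries where they changed with TMM scaling. Of 30 interferon response genes 15 fell and none rose, also adjusted over the list alone, and 10 fell with library totals alone and 7 with FPKM (list adjusted p = 0.000388; adjusted p = 0.646 with an estimated correlation and 0.107 with fry). The antiviral genes Oas3 (-3.25 ± 0.40) and Isg15 (-2.51 ± 0.37) and Ifi27 (-1.93 ± 0.12) fell most. Young 3 stood apart for Oas3 (21.9, 21.7 and 7.43 CPM in young 1, 2 and 3) and Isg15 (18.7, 22 and 7.86 CPM), and Ifi27 overlaps Ifi27l2a over 6057 bases. Antigen presentation genes fell in 10 and rose in 6 of 22, or 11 and 6 adjusted over the list alone and 6 and 6 with library totals alone (list adjusted p = 0.17, and 0.0177 without old 2). Psmb9 (-1.44), a subunit of the immunoproteasome, and B2m (-1.21) fell, and the class II gene H2-Ab1 (1.17) rose. Complement genes fell in 6 of 19 and C1qc rose, also adjusted over the list alone, with a median of -0.11 that is 0.17 with library totals alone (list adjusted p = 0.0856, and 0.0193 without old 2). The central component gene C3 fell from 33.1 ± 2.19 to 7.52 ± 2.49 CPM. Cytokine and chemokine genes fell in 5 of 23 and 1 rose, or 4 and 1 adjusted over the list alone, 2 and 1 with library totals alone and 1 and 1 with FPKM (list adjusted p = 0.306). The B cell attractant gene Cxcl13 had a ratio of old to young of 42.3 (95% interval 14.1 to 208; fitted value 5.22, or 6.03 without young 2), and Ccl6 (-1.51), Nlrp3, Ccl9, Vcam1 and Il18 fell. Nlrp3 (-1.10) passed neither without young 2 (adjusted p = 0.0526) nor without young 3 (adjusted p = 0.0951), and Ccl9 (-1.03) not without young 2 (adjusted p = 0.0566), nor either with library totals alone (adjusted p = 0.0567 and 0.0675). Il18 (-0.54) passed only without young 1 among the sets of 5 libraries (adjusted p from 0.0657 to 0.196 in the others), and not with upper-quartile scaling, library totals alone or TMM on protein-coding genes (adjusted p = 0.0775, 0.302 and 0.116). Of 20 senescence genes 10 fell and 3, Igfbp7, Rb1 and Sirt1, rose, also adjusted over the list alone, or 7 and 4 with library totals alone (list adjusted p = 0.0807). Igfbp7 did not pass without young 2 or old 2 (adjusted p = 0.053 and 0.0658). The collagenase gene Mmp13 (-3.96) and the cell cycle inhibitor gene Cdkn1a (-1.04) fell.

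Genes of cell division, energy metabolism and protein synthesis were lower in the old libraries, in which the library totals and the neutrophil, erythroid and B lineage genes (list medians -3.43, -2.88 and -2.38) were also lower. Of 30 proliferation genes 27 fell and 1, Tyms, rose, with a median of -1.76 (list adjusted p = 1.17e-09; adjusted p = 0.419 with an estimated correlation). The topoisomerase gene Top2a (-3.36 ± 0.37), Ube2c (-3.19 ± 0.29) and Rrm2 (-3.13 ± 0.41, or -3.72 without old 3) fell most. Replication histone genes fell in 18 of 27 cases with a median of -1.57 (list adjusted p = 3.38e-09; adjusted p = 0.351 with an estimated correlation), and 1 rose with library totals alone. Of 42 nuclear-encoded oxidative phosphorylation genes 40 fell, or 37 with library totals alone (list adjusted p = 4.43e-21; adjusted p = 0.325 with an estimated correlation). Ndufa1 (-2.01 ± 0.19) and Cox4i1 (-1.71 ± 0.13), of respiratory complexes, fell most, Cox4i1 from 385 ± 69.7 to 117 ± 9.58 CPM. Of 41 cytosolic ribosomal protein genes 36 fell, or 38 with 1 risen adjusted over the list alone (list adjusted p = 7.27e-18; adjusted p = 0.344 with an estimated correlation). Rps28 (-1.96) and Rplp2 (-1.63) fell most. Antioxidant genes fell in 28 of 32, or 29 adjusted over the list alone, and in 18 with 2 risen under library totals alone (list adjusted p = 1.17e-09; adjusted p = 0.325 with an estimated correlation). The peroxide-removing enzyme genes Gpx1 (-1.52 ± 0.09) and Prdx3 (-1.40 ± 0.10) fell most. Collagen and matrix genes fell in 20 of 34 (list adjusted p = 4.52e-07; adjusted p = 0.32 with an estimated correlation), with 15 fallen and 1 risen under library totals alone. Col1a1 (-3.46, or -2.87 without young 3) and Col3a1 (-2.08) fell most. Col1a1, Col1a2 and Sparc are also in the osteoblast list, so the collagen list is not independent of it. The counts of the division, histone, phosphorylation and collagen lists were the same adjusted over the list alone. Across coding genes, which are not independent replicates, fold change rose with implied length (Spearman correlation 0.25). With length offsets the histone, phosphorylation, ribosomal and antioxidant medians were -1.12, -0.69, -0.67 and -0.61, in place of -1.57, -0.9, -0.91 and -0.75. Those of proliferation and collagen were -1.89 and -0.82, in place of -1.76 and -0.47.

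Heat shock, apoptosis and autophagy genes fell more often than they rose, and immediate early genes rose more often than they fell. Heat shock and unfolded protein genes fell in 15 and rose in 4 of 27, or 8 and 4 with library totals alone (list adjusted p = 0.0154; adjusted p = 0.688 with an estimated correlation and 0.118 with fry). The list did not pass without old 2 (adjusted p = 0.0579). The chaperonin gene Hspe1 (-1.56) fell, and Atf3 (0.57) and Ddit3 (0.42) rose. Atf3 did not pass without young 1, young 2, old 1 or old 3 (adjusted p = 0.102, 0.114, 0.0804 and 0.122). The inducible chaperone genes Hspa1b (2.13) and Hspa1a (1.75) rose, but without old 1 they stood at 0.50 (adjusted p = 0.417) and 0.53 (adjusted p = 0.154). They also missed the threshold without young 1 (adjusted p = 0.0844 and 0.0595) and young 2 (adjusted p = 0.102 and 0.0723), and Hspa1b was 2.95 without young 3. Apoptosis genes fell in 12 of 26 and none rose, but 6 fell and 5 rose with library totals alone (list adjusted p = 0.0156; adjusted p = 0.32 with an estimated correlation). With genes of a mean count of at least 50 alone that list did not pass (adjusted p = 0.0652). Ripk3 (-2.21) and the mitochondrial pore gene Bax (-1.56) fell most. Autophagy genes fell in 19 and rose in 1 of 29, or 11 and 5 with library totals alone (list adjusted p = 0.000156; adjusted p = 0.334 with an estimated correlation). Gabarapl1 (-1.11), Map1lc3b (-0.87) and the lysosomal protease gene Ctsl (-0.84) fell. Immediate early genes rose in 11 and fell in 2 of 23 (list adjusted p = 0.0587; without young 2, young 3, old 1 and old 2 in turn 0.0361, 0.0267, 0.0334 and 0.0499), Klf4 (1.05), Klf2 (1.01) and Jun (0.85) rising and Btg2 (-0.94) and Ier3 (-0.70) falling. Ier3 did not pass without old 1 (adjusted p = 0.0516) or with library totals alone (-0.41; adjusted p = 0.0973). Clock genes did not pass as a list (adjusted p = 0.802), with 3 of 19 higher and 4 lower, 3 and 0 adjusted over the list alone, and 6 and 0 with library totals alone. Rora (0.79 ± 0.07) rose, and Nr1d2 (-0.32), Hlf (-0.25) and Per1 (-0.24) fell, but stood at -0.04, 0.03 and 0.05 with library totals alone (adjusted p = 0.781, 0.825 and 0.649), and passed neither with upper-quartile scaling (adjusted p = 0.0947, 0.137 and 0.147) nor with TMM on protein-coding genes (adjusted p = 0.177, 0.301 and 0.349). Without young 2, old 1 and old 3 in turn, the adjusted p was 0.0737, 0.0513 and 0.0843 for Nr1d2, 0.179, 0.076 and 0.132 for Hlf, and 0.113, 0.145 and 0.0893 for Per1, which also missed it without young 3 (0.121) and old 2 (0.0581). Per2 (0.91) did not pass without old 1 (adjusted p = 0.0577) or old 2 (adjusted p = 0.0544), nor Nr1d1 (-0.71) without young 3 (adjusted p = 0.115), old 1 (adjusted p = 0.104) or old 3 (adjusted p = 0.0775) or with library totals alone (adjusted p = 0.171). The counts of the other lists here were the same adjusted over the list alone.

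Imprinted genes outside the Dlk1-Dio3 region rose in 10 and fell in 5 of 19 cases, also adjusted over the list alone, or 8 and 7 with length offsets, and the list did not pass (adjusted p = 0.345). The long noncoding Airn (21.9 ± 1.4 to 68.6 ± 3.43 CPM) and Kcnq1ot1 (174 ± 16.5 to 420 ± 41.3 CPM), which silence neighbouring genes, rose and overlap the imprinted Igf2r and Kcnq1, so their values are uncertain too, and Kcnq1ot1 stood at 0.11 with length offsets (adjusted p = 0.345). H19, the growth factor gene Igf2 (-1.18), Nnat (-1.73), Grb10 (-0.67) and Igf2r (-0.49) fell. Of 7 tested Foxp and Foxo genes, Foxp1 rose and Foxo4 (-0.47 ± 0.11) fell, also adjusted over the list alone, while library totals alone gave 3 higher and 0 lower, with Foxo4 at -0.20 (adjusted p = 0.155). That list did not pass (adjusted p = 0.639), and its median of -0.14 had the opposite sign to its mean of 0.11 and its test, which pointed higher. The study chose Foxp1 and Mirg, so their places in these lists are not independent evidence. Of 39 tested lists 4 were higher and 21 lower with the preset correlation, and none passed with an estimated correlation, where the smallest adjusted p was 0.32 and 6 lists had an unadjusted p under 0.05. With fry, which tests each list on its own, 24 passed. It does not compare the members with other genes, of which many changed too (54.2% of all tested). A pass in fry thus does not set a list apart from the other genes.

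**Figure D3:**
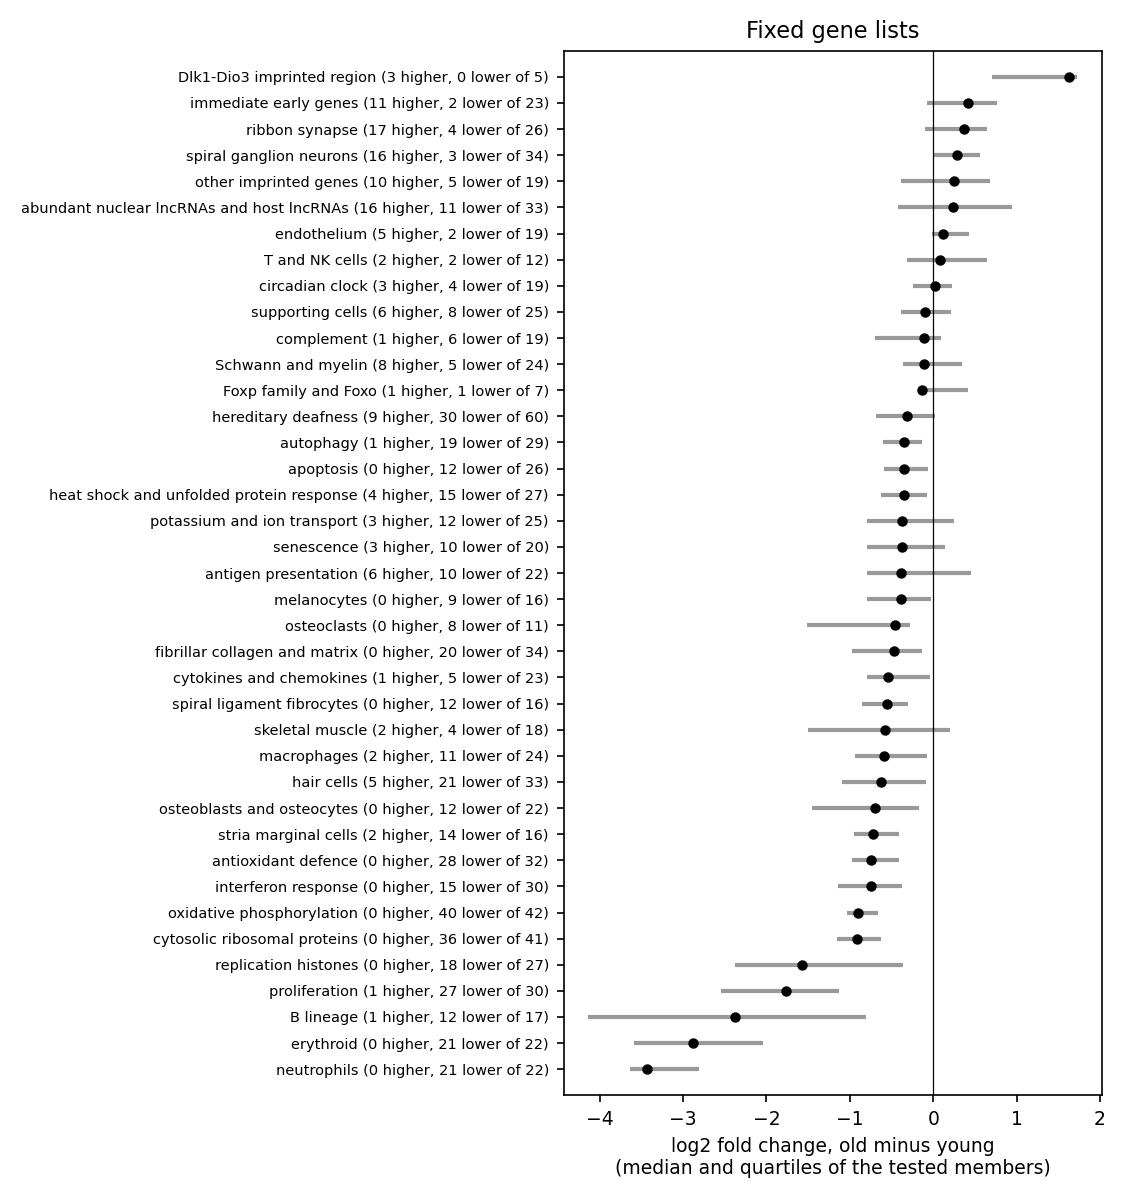
Median (point) and quartiles (bar) of the log2 fold change, old minus young, over the tested members of each of the 39 gene lists, with the numbers of members higher and lower beside each name. Neutrophil genes have the lowest median (-3.43) and those of the Dlk1-Dio3 region the highest (1.63) with TMM scaling; with library totals alone the medians of supporting cells, Schwann and myelin, complement and Foxp and Foxo genes change from negative to positive, potassium and ion transport genes do so with FPKM, and the clock median of 0.02 is -0.05 with length offsets.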

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

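Of the tests in this part, the share of marrow and blood markers, thinning, the length offsets, library totals without the highest features, the places of long noncoding genes, the left-out sex chromosomes and the circular RNAs' own totals were chosen only after the result was seen.

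The count table also holds circular RNAs, which the comparison of genes does not use, and some differed between the age groups. Of 4909 tested in edgeR, 251 were higher and 909 lower in old libraries, and 1655 had an unadjusted p under 0.05. With the totals of the circular RNAs themselves 401 were higher and 557 lower, and the median log2 fold change was -0.15 in place of -0.44. Higher in old libraries were mmu_circ_0007969 (0.28, 0 and 0 CPM in young 1, 2 and 3 against 23.76, 35.23 and 24.43 in old 1, 2 and 3) and mmu_circ_0007967 (3.49 ± 0.30). Lower were mmu_circ_0012312 (-3.04 ± 0.34) and mmu_circ_0014252 (-2.93 ± 0.33). Without young 1, young 2 and young 3 in turn, 243, 61 and 67 were higher and 499, 237 and 262 lower. Without old 1, old 2 and old 3 in turn, 148, 110 and 135 were higher and 900, 884 and 951 lower. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the split by age, gave as many. It gave 1160 and the highest of the others 0, and 10 splits are too few for a share under 0.05. The other splits also mix old and young libraries within their groups, which widens the spread there, so their 0 does not show what a random grouping would give.

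Long noncoding genes were higher in old libraries, 1385 against 109 lower. With each library thinned to the same total 92.8% of the changed ones were higher. Thinning leaves expected fold changes as they are, so it cannot decide whether depth plays a part. With length offsets 91.3% were higher, which argues against a length trend common to all genes as the whole cause. Across the long noncoding genes alone, fold change rose with implied length (Spearman correlation 0.328), and a trend particular to that class was not corrected. A larger share of unspliced or nuclear RNA in the old libraries is an open candidate explanation. Across genes, which are not independent replicates, the partial Spearman correlation of fold change with genomic span at equal implied length was 0.114 for coding and 0.091 for long noncoding genes, near the value of 0.1 asked of both. Of 759 long noncoding genes inside a coding gene's span 69.3% rose, against 42.2% of 650 with partial overlap and 43.2% of 1354 without overlap. Age and sex of the animals also stay open, untested.

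Neutrophil, erythroid, B lineage and proliferation lists were lower in old libraries. After each library was thinned to the same total, 4 of 4 lists kept a median below 0. Their list adjusted p was then at most 0.000106 in camera with the preset correlation. Thinning draws the same share of counts from every gene of a library. It thus leaves expected fold changes as they are, and cannot decide whether depth plays a part. Before thinning none of these lists passed with an estimated correlation (adjusted p from 0.32 to 0.419). A lower share of marrow and blood cells in the old tissue stays open: 58 of 61 tested members of the first 3 lists (95.1%) had a log2 fold change below 0, which restates the pattern and decides nothing. The abundant Hba-a1 (1330 to 347 CPM), Hbb-bs (860 to 152), Ngp (233 to 23.9) and Ltf (153 to 12.2) were lower. Ebf1, the most abundant member of the B lineage list, was higher (232 to 377 CPM). It stood far above the next member, Rag1 (7.39 to 1.89 CPM), so whether its RNA came from B cells is not known. Less of a single mixture of fixed make-up stays open, as the list medians differ by up to 1.05 with overlapping quartiles, and so do age and sex, untested.

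Of the tested genes 54.2% differed between the age groups. Gene dosage of the sex chromosomes was checked by position: 322 changed genes, 2.9%, lie on X or Y, and 10593 genes passed with those chromosomes left out. Only 589 and 6 of the 20157 tested genes lie on X and Y, so no large share was possible. Most changed genes thus lie elsewhere, and effects of the sex chromosomes on them were not tested. A few features with many counts were checked with library totals alone. Leaving out globins and the 10 highest features moved the median log2 fold change by 0.126, and 10905 genes passed in place of 11179. The number of changed genes thus hardly depended on these features. Their direction did: 6895 were higher and 4010 lower without these features, in place of 8259 and 2920. Sex of the animals cannot be told apart from age, because Xist and Y-linked counts follow the age group in 6 of 6 libraries, and age itself stays open, untested. In 1 of 10 splits, that by age, as many genes changed (10923, highest other 0), as many by at least 2-fold (3499, highest other 0) and as many long noncoding genes (1494, highest other 0). In 3 of 10 splits as many lists passed (25, lowest other 13 and highest other 33), so lists were called where no gene was. The 10 splits are too few for a share under 0.05. Every other split also mixes old and young libraries within its groups, so the difference between the age groups widens the spread there. Calls of 0 in those splits thus do not show what a random grouping of like libraries would give.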

How the results depend on the processing

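The alternatives added only after the results were seen were the omission of genes of X and Y, inclusion of circular RNAs, thinning, TMM on protein-coding genes, length offsets, library totals without globins and the 10 highest features and the circular RNAs' own totals. In simulated data with far fewer changed genes the fit called 44% of those changed by 1.5-fold. That share does not give the sensitivity of the fit to the measured data. With each library thinned to the same total 10651 genes changed in place of 10923. Mirg and Foxp1 were higher in old libraries under every setting run, at log2 fold changes from 1.48 to 2.01 and from 0.81 to 1.32. With library totals alone 8259 genes were higher and 2920 lower, 3550 and 740 of them by at least 2-fold, and 59 long noncoding genes were lower. With a mean count of at least 50, which tests fewer genes, 1363 and 799 changed by at least 2-fold and 895 and 61 long noncoding genes changed. On log2(FPKM + 1), 2660 genes were lower, 1067 and 326 changed by at least 2-fold, 66 long noncoding genes were lower and 2 lists higher; without a filter 2499 were lower and 1048 and 308 changed by at least 2-fold. On log2(FPKM + 0.1), 2641 genes were lower, 560 by at least 2-fold, 62 long noncoding genes were lower and 2 lists higher. Of the genes changed under TMM, 35 to 40 were reversed with FPKM and 46 with length offsets; the cause was not tested. At an adjusted p under 0.01, 3599 genes were higher. In camera with an estimated correlation 0 lists were higher and 0 lower, 6 having an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 24 passed. Without 1 library each, 3939 to 5310 genes were higher and 4499 to 5911 lower, 1819 to 2400 and 1104 to 1432 by at least 2-fold. Long noncoding genes then numbered 1073 to 1354 higher and 71 (without young 2) to 123 lower, and lists 2 (without old 3) to 5 higher and 21 to 22 lower. With the replicate number as a block (replicate block), 4860 genes were higher and 5079 lower, 9837 of them shared with the fit without a block, but the numbers do not pair the libraries: correlations across genes of the deviations from the group means were -0.082, 0.026 and -0.057 for like numbers, and other pairs reached 0.12. Of 39 lists, those of spiral ganglion neurons, interferon response, heat shock and deafness did not pass with fry (adjusted p = 0.131, 0.107, 0.118 and 0.0538), while senescence, ion transport and other imprinted genes passed (adjusted p = 0.00179, 0.0222 and 0.0313). Immediate early genes passed with library totals alone (adjusted p = 0.0457), complement without a filter (adjusted p = 0.0324) and endothelium on log2(FPKM + 1) without a filter (adjusted p = 0.0224). No gene that was named under the rule and passed changed sign in any setting, and no list that passed had its test turn, but with FPKM the ion transport genes had 10 higher and 5 lower and those of hereditary deafness 20 and 15, and the medians of supporting cells, Schwann and myelin, complement and Foxp and Foxo genes turned positive with library totals alone. The medians of T and NK cell and clock genes turned negative without a filter.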

Other observations

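The families by symbol prefix, the X-linked partners of Y genes, the unnamed feature and the Dlk1-Dio3 test in this part were chosen only after the result was seen.

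Genes of the Sox family of transcription factors, which set the fate of neural crest, supporting and vascular cells, were higher in old libraries. Of 15 tested entries, Sox2ot included, 14 rose and none fell with TMM, and 12 rose and 1 fell with length offsets, the only scaling with a fall. All 2467 bases of Sox2 lie within Sox2ot and strandedness is not given, so these 2 entries are not independent. Sox10 of glia and melanocytes rose from 241 ± 19.4 to 384 ± 10.2 CPM, Sox9 (0.49 ± 0.08) and Sox5, Sox6, Sox4, Sox12, Sox13, Sox7, Sox21 and Sox11 rose by 0.33 to 1.09 on the log2 scale, beside Sox2, Sox17 and Sox18. Sox8 was at -0.30 (adjusted p = 0.0949). Among 101 families of at least 15 tested genes that share a symbol prefix, 26 passed with the preset correlation. The Sox family had an adjusted p of 2.99e-05, and of 0.352 with an estimated correlation. Zinc finger genes (Zfp) rose in 133 and fell in 18 of 379, or 246 and 3 with library totals alone and 107 and 35 with length offsets. Centrosome genes (Cep) rose in 19 and fell in 3 of 40, or 30 and 1 with library totals alone and 14 and 6 with length offsets. Solute carriers (Slc) fell in 146 and rose in 26 of 298, or 79 and 52 with library totals alone. RNA polymerase subunits (Polr) fell in 18 and rose in 0 of 28, or 11 and 1 with library totals alone, and mitochondrial ribosomal proteins (Mrpl) fell in 26 and rose in 3 of 49, or 15 and 7. Aldehyde dehydrogenases (Aldh) fell in 13 and rose in 1 of 18, or 10 and 2 with library totals alone, and tetraspanins (Tspan) fell in 15 and rose in 1 of 20, or 9 and 2. None of these passed with an estimated correlation (adjusted p from 0.29 to 0.609).

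The X-linked relatives of Ddx3y, Eif2s3y, Kdm5d and Uty, the 4 Y-linked genes that rose, fell in old libraries. Ddx3x fell from 548 ± 27.5 to 233 ± 24.2 CPM (log2 fold change -1.23 ± 0.09) and Eif2s3x from 181 ± 1.81 to 91.8 ± 7.57 CPM (-0.98 ± 0.08). Kdm5c (-0.75 ± 0.08) and Kdm6a (-0.66 ± 0.08) fell as well, and the 4 also fell with library totals alone. Of other X-linked genes with Y-linked relatives, Uba1 (-0.62 ± 0.08), Zfx (-0.28 ± 0.08) and Usp9x (-0.18 ± 0.07) fell and Rbmx (0.25 ± 0.08) rose. With library totals alone Zfx (0.00; adjusted p = 0.963) and Usp9x (0.09; adjusted p = 0.359) did not pass. In the young libraries, young 1 held more central myelin RNA than the others: Mobp had 104 CPM there against 15.5 and 7.61, and Mog 15.3 CPM against 2.53 and 1.61. The unnamed feature BGIG10090_59442, with an implied length of 77 bases, fell from 90400 to 14300 CPM (-2.66 ± 0.20).

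That the whole Dlk1-Dio3 region is higher in old libraries was tested as a hypothesis: of 5 tested members 3 passed and were higher, and Dio3os and Begain had positive values that did not pass. With library totals alone both passed (0.98 and 0.69; adjusted p = 0.0461 and 0.0391). The hypothesis stays open. Of 173 genes named under the rule, 66 overlap another annotated gene, which leaves their values uncertain without known strandedness.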
